A study of Mus musculus with 36 samples.

How the data were processed

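Cells of the haematopoietic stem and progenitor compartment were sorted from mice carrying Kmt2a-AFF1, a fusion of a histone methyltransferase gene with a transcription elongation gene that occurs in infant leukaemia. Total RNA of the sorted cells was made into stranded total RNA libraries from very small inputs, per the labels' protocols. The 36 libraries fell into 9 groups of 4. In the leukaemia arm, mice overexpressing a microRNA (miR-130b in the sample labels, miR-130a in the design text of the series) gave bone marrow (BM) and central nervous system (CNS) cells of 3 sorted types. These types were HSC/MPP (stem cells and multipotent progenitors, Sca-1 positive and Flt3 negative), LMPP (lymphoid-primed progenitors, Sca-1 and Flt3 positive) and LK (Sca-1 negative progenitors, labelled LK/CLP), called HSC, LMPP and LK here. Each of the 12 leukaemia mice gave 1 BM and 1 CNS library of a single cell type. In the control arm, BM of 4 mice carrying the same fusion with a scrambled microRNA gave 1 library of each cell type per mouse.

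The authors deposited 2 tables, 1 for the 24 leukaemia libraries and 1 for the 12 control libraries, with 55414 gene identifiers each. The table names call the values normalised, but the deposited values are whole counts whose totals differ between libraries, so they were treated as counts that had not been scaled. A test for normalised values, limma-trend, had been planned; because the values are counts, edgeR's quasi-likelihood test replaced it, and limma-trend became an alternative. Per the submitters' processing notes, DESeq2 was used and the genome build was GRCm39; the aligner, the counting tool and its strand setting are not given in the sources used here. Genes that overlap, antisense genes and members of families with near-identical copies are therefore uncertain. Symbols were matched by identifier to a reference annotation of another mouse build: 52081 identifiers had a symbol and 3333 had none. Exon lengths, for 52133 identifiers, were also computed from an annotation of that build. Levels and fold changes in the report come from each table by itself. The 2 tables were joined for the test of whether cell type differences depend on disease and, among the closing observations, for log2 differences of fusion targets between leukaemia and control.

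Library totals ran from 1.91 to 30.4 M counts (M, the prefix mega). Sensory receptor genes, taken here without a test as not expressed in the sorted cells, carried counts in every library. Their counts per kb, over 1469 such genes, set for each library the level of a uniform background along the genome. The share that this background would bring is given as a percentage of the counts of identifiers with an exon length. A gene was said to lie above background when its count exceeded 3 times the background for its length plus 10 counts in at least 4 libraries. That left 15866 genes in the leukaemia table, 11179 in the control table and 15306 in BM libraries of both. Identifiers without an exon length could not pass this filter, which was chosen after seeing the data.

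For each comparison, libraries were scaled by trimmed mean of M values and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. Genes with at least 10 counts in at least 4 libraries entered, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. An "edgeR adjusted p" is such a value. In the principal test all libraries of a table shared an estimate of the spread and no mouse term was used. The paired test added the mouse as a block. BM and CNS libraries with the same cell type and number come from the same mouse, as do control libraries with the same number, so these numbers pair the samples. Deviations from the group means correlated within the 12 leukaemia pairs with a median of 0.26 (range -0.50 to 0.68), and 8 of 12 libraries correlated best with their own partner. For the 12 control pairs the median was -0.02. Libraries of different leukaemia cell types share only a number. The paired test on genes above background, and the unpaired test on genes above background for cell types, are the added alternatives whose named genes are given most often in the report.

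There were 42 gene lists; 832 of their 834 genes were matched. They cover metabolic, stress, signalling and cell cycle pathways, blood lineages, and markers of other cell types that a sort of BM or CNS could hold. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data; "camera adjusted p" is the first, adjusted over the lists. Members were also counted after adjustment over all genes tested and over the list alone.

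Groups, contrasts, the models of the principal and paired tests, the gene lists and the following rule for named genes were fixed before the data were examined. The plan named limma-trend, with edgeR in its place if the values were counts. The rule takes the largest rises and falls among genes past the threshold (12 each way for the niche comparison over all cell types, 6 each way elsewhere) that moved the same way in at least 10 of 12 mice, in all 4 mice, or without overlap between groups, with a mean count of at least 50. Where no gene passed, it takes the 5 of smallest p; for F-tests, the 8 of smallest p; for lists, up to 4 members; and Kit, Ly6a and Flt3 in each comparison of cell types. Some genes that the rule takes are not reported here. Errors beside log2 fold changes are standard errors of the fit; CPM are counts per M counts of genes above background after scaling, given as group means.

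Alternatives were DESeq2 1.42.0, no count filter, limma-trend with pseudocount 5, array weights, quantile scaling, median centring, only the groups compared, the first number of the mouse identifier as a block, and leaving out each library. Added after seeing the data were limma-trend with pseudocount 1, the filter on background, the background level as a covariate, leaving out each mouse, and the omission of BM LMPP replicate 3 (few counts) and CNS HSC replicate 1 (macrophage genes). The procedure was tested on simulated counts with 2-fold and 4-fold changes. For the niche comparison in LMPP, the principal test recovered 0 of 94 genes changed 2-fold and 16.2% of those changed 4-fold. For the niche comparison over all cell types it recovered 10.5% and 67.4%, and the paired test on genes above background 75 and 100 of 100. For HSC against LK the figures were 0 of 96 and 13.7% in CNS, and 39.6% and 91.8% in control BM. No changed gene was called with the wrong sign, and at most 10 unchanged genes were called in a simulation. The simulated counts held no mouse effect, no differences in background and no outlying library, so recovery in the real data may differ. Figures were drawn with matplotlib 3.10.9. Mature microRNAs are too short for this library type: the Mir130b gene had 0 to 9 counts and Mir130a 0 to 4 counts in leukaemia libraries, and both had 0 to 7 in controls, so the overexpression itself was not assessed.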

Results

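Gene expression was measured in 36 libraries of sorted mouse blood stem and progenitor cells, 4 in each of 9 groups. The 12 leukaemia mice gave HSC, LMPP or LK cells from bone marrow (BM) and central nervous system (CNS), and the 4 control mice gave all 3 cell types from BM. Counts per library ran from 1.91 M in BM LMPP replicate 3 to 30.4 M in BM LMPP replicate 1, and from 3.55 to 21.6 M in the controls. Background along the genome was estimated at 21.6 to 27.7% of counts in control HSC, 14.1 to 26.9% in control LMPP and 6.48 to 12.3% in control LK. In leukaemia libraries it ranged from 0.443% in CNS LMPP replicate 4 to 26.5% in BM HSC replicate 4. The mean was 13.4 ± 8.71% (SD, n = 4) in BM HSC, 2.68 ± 2.49% in BM LMPP and 5.48 ± 3.78% in BM LK. In CNS the means were 13.8 ± 8.57%, 3.55 ± 3.48% and 4.78 ± 4.29%. Background was thus highest on average in HSC in leukaemia and separated LK from the rest in controls, where HSC and LMPP overlapped. Identifiers without a symbol held 8.34 to 47.4% of counts. Since background is a percentage of the counts of identifiers with an exon length, it overstates the uniform share of all counts, by an amount that differs between libraries. Each gene entered it only up to the uniform level, so counts above that level are left out. The predicted gene Gm10800 alone averaged 20.1% of counts in control HSC, 22.2% in control LMPP and 4.73% in control LK. It reached 28.8% in CNS HSC replicate 4. Whether these counts are background was not tested.

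**Figure D1:**
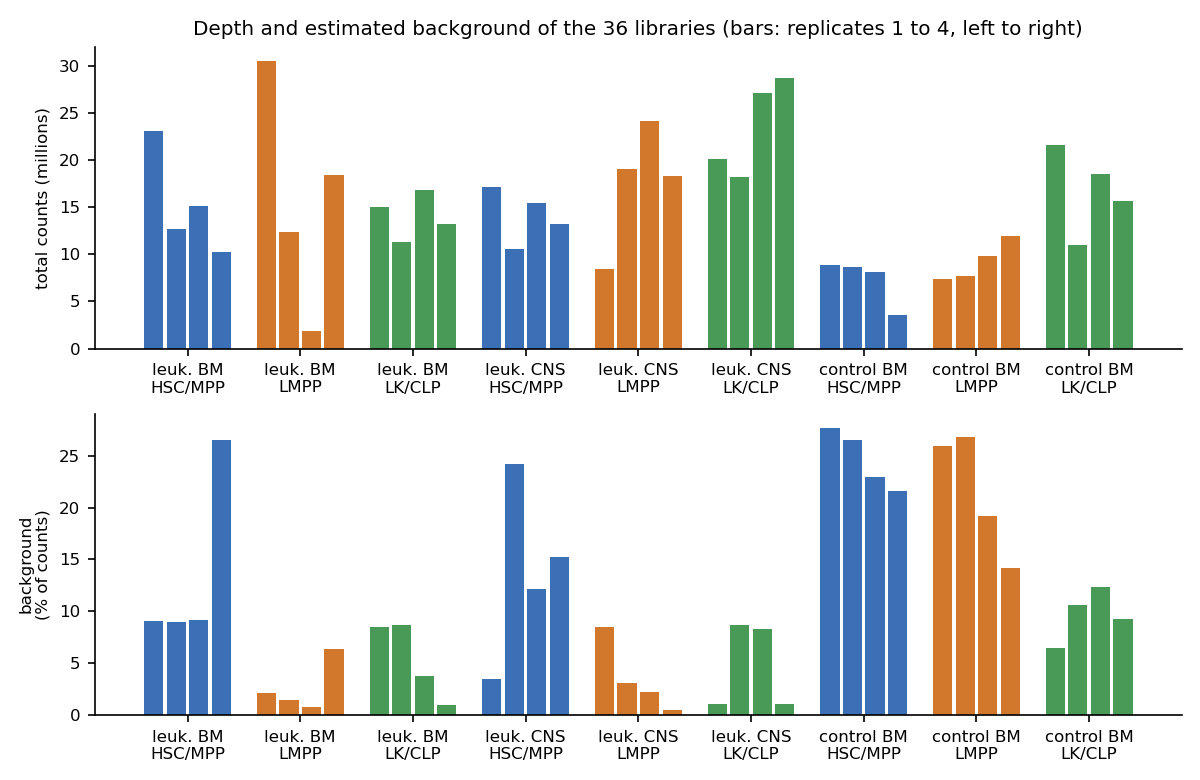
Total counts (M) and estimated background (% of counts of identifiers with an exon length) of each of the 36 libraries, by group. Control HSC and LMPP libraries carried 14.1 to 27.7% background, and BM LMPP replicate 3 held 1.91 M counts, the fewest of all libraries.

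The first question was how expression of leukaemia cells differed between CNS and BM of the same mouse. In the paired test on genes above background, which was chosen after seeing the data, H2-Eb1, a chain of MHC class II, rose from 174 to 601 CPM. Its log2 fold change was 1.75 ± 0.26 (edgeR adjusted p = 0.00663, higher in 12 of 12 mice). Hspa1b, an inducible heat shock chaperone, rose from 16.5 to 53.1 CPM (1.65 ± 0.17, edgeR adjusted p = 0.000832, 12 of 12 mice). Olfm1, a secreted glycoprotein known from neurons, rose from 20.7 to 69.0 CPM (1.72 ± 0.20, edgeR adjusted p = 0.00305, 12 of 12 mice). Apoe, a lipid carrier abundant in macrophages, rose from 16.3 to 129 CPM (1.98 ± 0.41, edgeR adjusted p = 0.0339, 11 of 12 mice), with 743.5 CPM in CNS HSC replicate 1 and 4.72 to 196 CPM in the other CNS libraries. The lysosomal protease Lgmn (1.86 ± 0.32) and the RNA sensor Tlr3 (1.58 ± 0.31) rose in 11 of 12 mice, as did Il13ra1, Basp1 and Cd300c2 by 1.63 to 1.92. Klrb1b (1.68 ± 0.33) and Sdc3 (1.65 ± 0.30) rose in 12 of 12 mice. Among genes that fell, Lrg1, a secreted glycoprotein of neutrophils, fell by 2.28 ± 0.46 (edgeR adjusted p = 0.0199, 11 of 12 mice). Adgrg3, an adhesion receptor, fell by 0.69 ± 0.11 from 235 to 148 CPM, and Gem, a small GTPase, by 0.77 ± 0.13 from 97.2 to 56.5 CPM, each in 12 of 12 mice. Ly6c1, Cdh17, Ccdc125, Msantd3, Tmprss3, Myl10, Tbxa2r, Pdgfrb and Mgst2 changed by -0.93 to -0.69.

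That test called 386 of 15866 genes, 263 higher and 123 lower in CNS. The paired test on all genes called 53 higher and 1 lower (Lrg1), and DESeq2 called 66 and 13. The principal test, edgeR without the mouse, called 0 of 40332 genes, with 793 at an unadjusted p under 0.05. Its smallest p belonged to Lmna (log2 fold change 1.62 ± 0.30), Xcr1 (1.42 ± 0.27), Hepacam2 (1.50 ± 0.29) and Cd83 (1.63 ± 0.32), each with edgeR adjusted p = 0.126, and Lrg1 (edgeR adjusted p = 0.133). Without BM LMPP replicate 2 the principal test called 63 genes, without CNS HSC replicate 2 it called 13, and without CNS HSC replicate 4 or CNS LMPP replicate 4 it called 5. The count of 386 became 102 without HSC mouse 1, 185 without HSC mouse 3, 155 and 171 without LMPP mouse 1 or 3, and 152, 83 and 77 without LK mouse 2, 3 or 4. It was 59 (40 higher, 19 lower) without the mice of CNS HSC replicate 1, rich in macrophage genes, and BM LMPP replicate 3, with few counts.

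**Figure D2:**
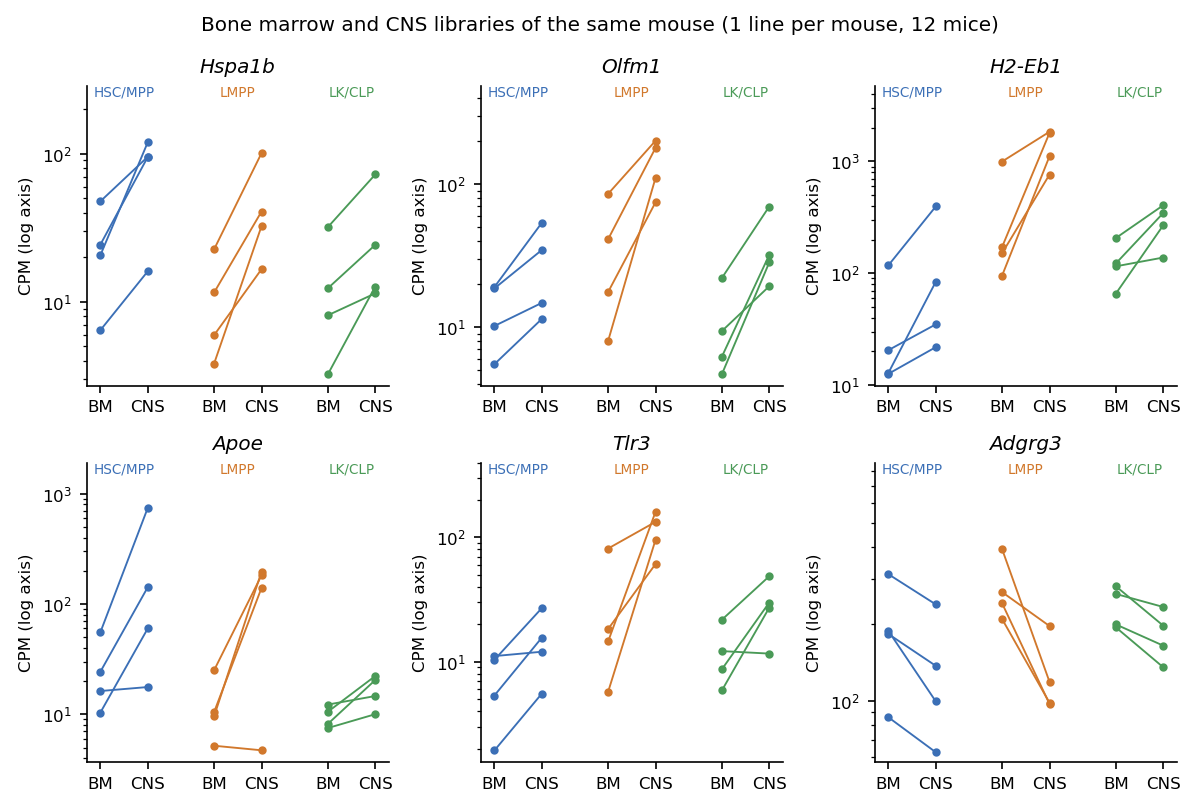
CPM on a log axis of Hspa1b, Olfm1, H2-Eb1, Apoe, Tlr3 and Adgrg3 in BM and CNS libraries; each line joins the libraries of 1 of the 12 leukaemia mice. Hspa1b, Olfm1 and H2-Eb1 were higher and Adgrg3 lower in CNS in 12 of 12 mice, Apoe and Tlr3 higher in 11 of 12.

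Of 42 gene lists, 21 passed the threshold over all cell types in the same paired test, 13 higher and 8 lower in CNS. Immediate early and heat shock genes had the smallest p: 23 of 24 were higher, 13 rose and 17 rose adjusted over the list alone (median log2 fold change 0.66, camera adjusted p = 2.44e-28). The list passed with adjusted p = 0.00662 with an estimated correlation. Ier5 rose by 1.14 ± 0.14 from 25.9 to 66.6 CPM (edgeR adjusted p = 0.00247), Hspa1a by 1.46 ± 0.19 and the transcription factor gene Junb by 0.86 ± 0.12. These genes are known to respond to tissue dissociation, and how long CNS and BM tissue were handled is not given in the sources used here. Cell cycle genes were lower in CNS in 36 of 36 cases (median -0.32, camera adjusted p = 1.1e-20; adjusted p = 0.235 with an estimated correlation); 2 fell, and 26 adjusted over the list alone. Kif11, a mitotic motor, fell by 0.54 ± 0.11 from 167 to 117 CPM (edgeR adjusted p = 0.0194). Histone genes, a family with near-identical copies and so uncertain one by one, were lower in 23 of 23 cases. Their median was -0.37, 4 fell, and 21 adjusted over the list alone (camera adjusted p = 1.51e-18; adjusted p = 0.235 with an estimated correlation).

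Genes induced by type I interferon were higher in CNS in 26 of 29 cases; 4 rose, and adjusted over the list alone 12 rose and 1 fell (median 0.29, camera adjusted p = 1.85e-09; adjusted p = 0.238 with an estimated correlation). Ifi204 rose by 1.08 ± 0.19 and Ifit3 by 1.56 ± 0.31. Of 29 interferon gamma and antigen presentation genes 6 rose, 7 adjusted over the list alone (median 0.10, camera adjusted p = 1.83e-05; adjusted p = 0.246 with an estimated correlation). Among them Cd74 rose from 764 to 2330 CPM (1.46 ± 0.22, edgeR adjusted p = 0.00453) and H2-Ab1 from 427 to 1388 CPM (1.56 ± 0.23, edgeR adjusted p = 0.00573). Of 19 targets of the Kmt2a fusion 17 were lower (median -0.26, camera adjusted p = 3.3e-07; adjusted p = 0.238 with an estimated correlation). Runx2 fell by 0.53 ± 0.11 and Bcl2 by 0.49 ± 0.12, while Cpeb2 rose by 0.47 ± 0.11. Adjusted over the list alone, 1 rose and 3 fell. Of 15 lymphoid genes 13 were lower and Ighm fell, 4 adjusted over the list alone (median -0.20, camera adjusted p = 4.17e-05; adjusted p = 0.208 with an estimated correlation).

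Markers of other cell types differed between CNS and BM on average, though not in every mouse. The per-mouse median log2 ratio of CNS to BM was above 0 in 10 of 12 mice for border macrophage genes. For microglia genes it was above 0 in 9 of 12, with 2 of 4 in LK, and for mature neutrophil genes in 3 of 12. Border macrophage genes were higher in CNS in 8 of 8 cases (median 1.33, camera adjusted p = 4.42e-08; adjusted p = 0.208 with an estimated correlation); Apoe and Pf4 rose, and 5 adjusted over the list alone. Microglia genes were higher in 15 of 16 cases, 0 rose over all genes tested (edgeR) and 2 adjusted over the list alone (median 0.88, camera adjusted p = 1.32e-07; adjusted p = 0.246 with an estimated correlation). C1qb, a complement gene of macrophages, was at 3.10 CPM in BM and 35.3 CPM in CNS (2.06 ± 0.51, edgeR adjusted p = 0.0657), with 292 CPM in CNS HSC replicate 1 and 0.849 to 45.9 CPM in the other CNS libraries. Mature neutrophil genes were lower in 11 of 12 cases, 0 over all genes tested (edgeR) and 7 adjusted over the list alone (median -2.10, camera adjusted p = 2.55e-07; adjusted p = 0.235 with an estimated correlation). The granule gene Camp was at 258 CPM in BM and 34.9 CPM in CNS (-2.88 ± 0.81, edgeR adjusted p = 0.108). The neutrophil list averaged 221 counts per M in BM LMPP replicate 1 and 2.33 to 4.12 in the other BM LMPP libraries. In the principal test the last 3 lists held their direction, and border macrophage and neutrophil genes passed with adjusted p = 0.0428 with an estimated correlation.

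**Figure D3:**
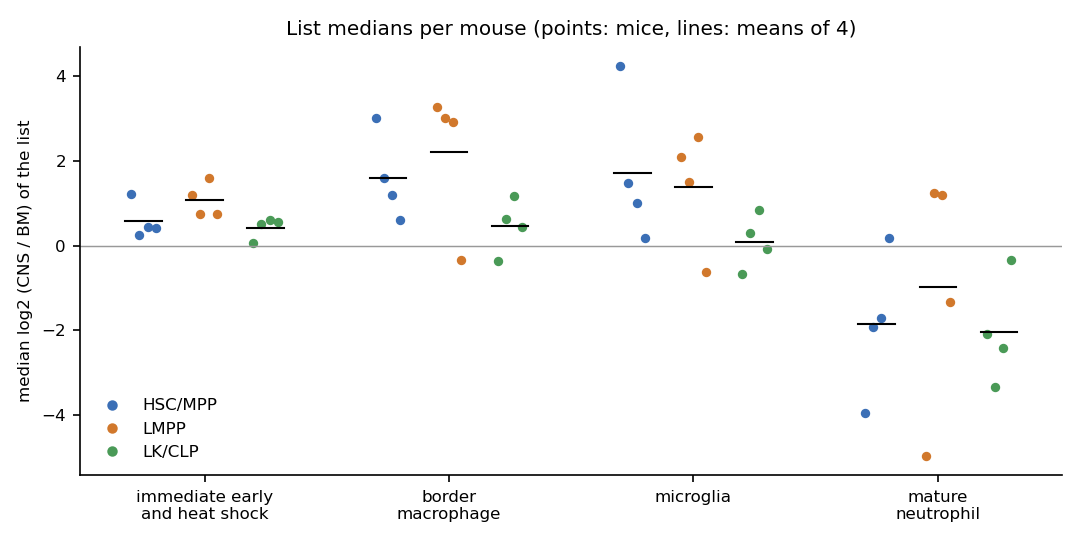
Median log2 ratio of CNS to BM over the members of 4 gene lists, 1 point for each of the 12 leukaemia mice, by cell type. Immediate early and heat shock genes lay above 0 in 12 of 12 mice, with LMPP mouse 3 highest at 1.60; microglia genes reached 4.22 in HSC mouse 1.

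In HSC cells no gene passed. Hspa1b was at 24.8 CPM in BM and 81.5 CPM in CNS (log2 fold change 1.72 ± 0.28, edgeR adjusted p = 0.305), Hspa1a differed by 1.69 ± 0.32 and Jun by 1.59 ± 0.33. Of genes with the smallest p in the principal test, Itgb5, Lgmn, Cx3cr1 and Olfml3 are known from macrophages and microglia, with log2 fold changes of 2.92 to 3.84 (edgeR adjusted p = 1). Cx3cr1, a chemokine receptor of microglia, was at 25.4 CPM in BM and 130 CPM in CNS, with 369 CPM in CNS replicate 1 and 20.6 to 95.2 CPM in the others. Of 16 microglia genes 15 were higher in CNS (median 1.63, camera adjusted p = 1.37e-12; adjusted p = 0.42 with an estimated correlation) and 1 rose adjusted over the list alone. The per-mouse medians were 4.22, 1.47, 0.99 and 0.17, and the list averaged 132 counts per M in CNS HSC replicate 1 beside 10.5 to 19.8. Immediate early and heat shock genes were higher in 22 of 24 cases, 6 rose adjusted over the list alone (median 0.58, camera adjusted p = 1.39e-13; adjusted p = 0.0921 with an estimated correlation). Ribosomal protein genes, a family with many near copies, had a median of -0.32 (camera adjusted p = 5.45e-11; adjusted p = 0.653 with an estimated correlation). For these 4 pairs edgeR called 0 genes in the principal test (300 at an unadjusted p under 0.05), 0 in the paired test (208) and 0 in the paired test on genes above background (1035); DESeq2 called 0 (513).

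In LMPP cells H2-Eb1 rose in CNS from 354 to 1378 CPM (log2 fold change 2.55 ± 0.46, edgeR adjusted p = 0.0214), H2-Ab1 from 864 to 3180 CPM (2.39 ± 0.42, edgeR adjusted p = 0.0167) and Cd74 from 1455 to 5201 CPM (2.32 ± 0.40, edgeR adjusted p = 0.0159), in 4 of 4 mice. Of the 29 interferon gamma and antigen presentation genes 22 were higher, 6 rose and 10 adjusted over the list alone (median 0.35, camera adjusted p = 8.39e-08; adjusted p = 0.212 with an estimated correlation). Hepacam2 rose from 3.34 to 27.6 CPM (3.02 ± 0.69, edgeR adjusted p = 0.0449). Fos, an immediate early gene, rose by 2.44 ± 0.52, the Wnt receptor Fzd1 by 2.54 ± 0.53, Lgmn by 2.73 ± 0.57 and Tbc1d9 by 2.42 ± 0.49. Adgrg3 fell by 1.14 ± 0.19 from 278 to 127 CPM (edgeR adjusted p = 0.0159), Pdgfrb, a growth factor receptor, by 1.35 ± 0.25 and Dach1, a transcription factor, by 1.40 ± 0.31. Tmprss3 (-1.44 ± 0.28) and Ptprf (-1.15 ± 0.26) fell too, and Runx2os2 (-1.63 ± 0.36) is uncertain as an antisense gene. Immediate early and heat shock genes were higher in 22 of 24 cases; 10 rose, 14 adjusted over the list alone (median 0.99, camera adjusted p = 4.2e-20; adjusted p = 0.0222 with an estimated correlation). Of 19 Kmt2a fusion targets 18 were lower and 3 fell, 9 adjusted over the list alone (median -0.61, camera adjusted p = 1.01e-11; adjusted p = 0.212 with an estimated correlation). Runx2 fell by 0.92 ± 0.19 from 330 to 179 CPM, Bcl2 by 0.95 ± 0.20 and Zeb2 by 0.92 ± 0.21. Type I interferon genes were higher in 25 of 29 cases, 5 rose and 9 adjusted over the list alone (median 0.41, camera adjusted p = 1.12e-07; adjusted p = 0.329 with an estimated correlation). Border macrophage genes had a median of 2.28 beside them, of which 2 rose adjusted over the list alone (camera adjusted p = 1.36e-05; adjusted p = 0.212 with an estimated correlation). These calls come from the paired test on genes above background, which gave 240 higher and 54 lower genes, 0 without LMPP mouse 1 or 3. It gave 502, 176, 184 and 186 without HSC mouse 2 or LK mouse 2, 3 or 4, and 1 without the mice of BM LMPP replicate 3 and CNS HSC replicate 1. The principal test called 0 genes (edgeR, 689 at an unadjusted p under 0.05), the paired test on all genes 0 (651) and DESeq2 5 higher and 4 lower. Without BM LMPP replicate 2 the principal test called 22, and without CNS LMPP replicate 4 it called 1.

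In LK cells Sept8, a septin, rose from 4.05 to 26.8 CPM in CNS (log2 fold change 2.79 ± 0.34, edgeR adjusted p = 0.00527, 4 of 4 mice) in the paired test on genes above background, and no other gene passed. Erythroid genes were higher in 14 of 16 cases, 0 over all genes tested and 7 rose adjusted over the list alone (median 1.43, camera adjusted p = 4.18e-17; adjusted p = 0.101 with an estimated correlation). Klf1, the erythroid transcription factor, was at 1.49 CPM in BM and 9.28 CPM in CNS (2.72 ± 0.48, edgeR adjusted p = 0.227), and the carbonic anhydrase gene Car2 at 17.4 and 51.9 CPM. The erythroid list averaged 33.7 counts per M in CNS LK replicate 1 and 8.27 to 11.0 in the other CNS LK libraries. In BM LK replicate 1, of the same mouse, the list averaged 19.9 beside 8.84 to 9.56 in the other BM LK libraries. Mast cell genes were higher in 8 of 8 cases (median 0.68, camera adjusted p = 4.11e-05; adjusted p = 0.218 with an estimated correlation), and genes of fatty acid synthesis in 14 of 14 (median 0.22, camera adjusted p = 0.00171; adjusted p = 0.218 with an estimated correlation). Granulocyte genes had a median of -0.37 (camera adjusted p = 1.41e-07; adjusted p = 0.381 with an estimated correlation). Immediate early and heat shock genes were higher in 21 of 24 cases, 6 rose adjusted over the list alone (median 0.55, camera adjusted p = 1e-09; adjusted p = 0.132 with an estimated correlation). The principal test called 0 genes (edgeR, 427 at an unadjusted p under 0.05; Sept8 3.06 ± 0.65, edgeR adjusted p = 1), the paired test called Sept8 alone and DESeq2 0 (666). With any 1 of the 4 LK mice left out, the paired test on genes above background called 0.

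Whether the niche difference depended on cell type was tested by its interaction. Sept8 had the smallest p (unadjusted 0.000691, edgeR adjusted p = 1), with Klf1, Hepacam2, Ttc39a, Itgb5 and Aqp1 among the 8 of smallest p. edgeR called 0 genes in the principal test (204 at an unadjusted p under 0.05), 0 in the paired test (286) and 0 in the paired test on genes above background (765), and DESeq2 called 0 (316). The alternative of limma-trend with array weights called 272 genes. By the edgeR and DESeq2 tests, the lists and genes given for a single cell type are therefore not shown to differ between types. Across genes above background, which are not independent replicates, niche fold changes of HSC and LMPP had a Spearman correlation of 0.28, HSC and LK 0.0016, and LMPP and LK 0.16.

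Among leukaemia BM cells, the sort markers followed the gates in part. Ly6a, the gene of Sca-1, rose in LMPP over LK from 2.65 to 33.2 CPM (log2 fold change 3.74 ± 0.63, edgeR adjusted p = 0.0352 in the principal test). On genes above background it also rose in HSC over LK, to 22.0 CPM (3.03 ± 0.53, edgeR adjusted p = 0.0382). Flt3 was at 73.3 CPM in HSC, 515 CPM in LMPP and 295 CPM in LK. It was lower in HSC than in LMPP by the test on genes above background (-2.81 ± 0.52, edgeR adjusted p = 0.0396). Kit, the receptor used to sort progenitors, differed between HSC and LK by -0.14 ± 0.32 (edgeR adjusted p = 0.821). Against LK, HSC held more F2r, a thrombin receptor (46.4 against 4.38 CPM, 3.39 ± 0.61), and more of the interferon-induced GTPases Irgm2 (1.42 ± 0.23), Gbp2 (1.83 ± 0.30) and Gbp5 (1.38 ± 0.24). Against LMPP, HSC held more Itga2b, an integrin of megakaryocytes (28.9 against 5.07 CPM, 2.35 ± 0.42), Gzmb (4.76 ± 0.89), Cd200r3 (3.04 ± 0.54) and Cd200r4 (2.56 ± 0.49). Parm1 (2.97 ± 0.54) and Auts2 (2.40 ± 0.44) were higher too, though Auts2 turned to -0.18 with median centring. Notch1, a receptor of lymphoid fate, was lower in HSC (138 against 322 CPM, -1.22 ± 0.22), as were Mctp2, Tcf19 and Tubgcp5 by -1.43 to -1.05 (edgeR adjusted p = 0.0433 for Tubgcp5).

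Type I interferon genes were higher in BM LMPP than in LK in 29 of 29 cases (median 0.92, camera adjusted p = 2.25e-33; adjusted p = 0.0274 with an estimated correlation); 16 rose adjusted over the list alone. Irf7 was at 25.1 CPM in LK and 117 CPM in LMPP (2.22 ± 0.39, edgeR adjusted p = 0.0526). Lymphoid genes were higher in 13 of 15 cases, 5 adjusted over the list alone (median 0.48, camera adjusted p = 4.11e-09; adjusted p = 0.0175 with an estimated correlation). Granulocyte genes had a median of -1.21 (camera adjusted p = 1.24e-16; adjusted p = 0.14 with an estimated correlation). HSC genes were higher in HSC than in LK in 12 of 13 cases, 4 adjusted over the list alone (median 0.90, camera adjusted p = 0.000461; adjusted p = 0.0516 with an estimated correlation). Mecom, a regulator of stem cells, was at 115 and 43.1 CPM. Histone genes fell in HSC in 23 of 23 cases adjusted over the list alone (median -0.96, camera adjusted p = 8.73e-16; adjusted p = 0.421 with an estimated correlation). Ribosomal protein genes had a median of -0.58 (camera adjusted p = 4.4e-14; adjusted p = 0.448 with an estimated correlation). Mast cell genes were higher in HSC than in LMPP, 8 of 8 adjusted over the list alone (median 2.20, camera adjusted p = 8.46e-08; adjusted p = 0.228 with an estimated correlation).

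In the principal test edgeR called 0 genes between BM HSC and LK (2371 at an unadjusted p under 0.05), 1 between LMPP and LK (Ly6a) and 2 between HSC and LMPP, both lower in HSC. Cox6a2, a subunit of cytochrome c oxidase, was among them (2.33 against 22.4 CPM, -4.07 ± 0.72, edgeR adjusted p = 0.0495). The test on genes above background called 5 higher and 0 lower, 1 and 0, and 6 and 5. DESeq2 called 65 and 18, 28 and 0, and 185 and 80. Scaling on genes above background moved these comparisons by 0.46, -0.12 and 0.58 log2. In the principal test HSC and LK differed by 2 genes without BM HSC replicate 4. LMPP and LK differed by 42 without BM LMPP replicate 1, and by 0 without any other LMPP or LK library. HSC and LMPP differed by 6 and 5 genes without BM LMPP replicate 1 or 4, and by 0 without any other library.

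In the CNS, Ly6a and Irf7 were higher in LMPP than in LK. Ly6a rose from 2.54 to 39.8 CPM (log2 fold change 4.18 ± 0.63, edgeR adjusted p = 0.00502) and Xcr1, a chemokine receptor of dendritic cells, from 16.9 to 109 CPM (2.84 ± 0.48, edgeR adjusted p = 0.0214) in the principal test. On genes above background Irf7, a regulator of interferon genes, rose from 36.9 to 241 CPM (2.71 ± 0.39, edgeR adjusted p = 0.0038). Slfn1 (2.92 ± 0.64), Cd83 (2.20 ± 0.48) and Parp12 (2.15 ± 0.35) rose with it. Lower in LMPP were Prg2 (3.05 against 93.1 CPM, -4.95 ± 1.07), Rab44 (44.2 against 306 CPM, -2.79 ± 0.57), Klf1 (-3.70 ± 0.67), Gata1 (-3.32 ± 0.66), Igfbp7 (-3.61 ± 0.54) and Cd200r4 (-3.02 ± 0.52); erythroid genes averaged 33.7 counts per M in CNS LK replicate 1 and 8.27 to 11.0 in the other CNS LK libraries. HSC held less Xcr1 than LMPP (11.5 against 109 CPM, -4.18 ± 0.51, edgeR adjusted p = 5.58e-05), and less of the peptidase gene Anpep (17.2 against 245 CPM, -4.87 ± 0.66) and of Tlr11 (9.18 against 86.8 CPM, -4.13 ± 0.66). Gpr141b, Gcsam and Rtl8c were also lower, by -5.49 to -4.23. Igfbp7 (3.20 ± 0.66), Cd200r4 (3.09 ± 0.66) and Cd200r3 (2.79 ± 0.59) were higher. On genes above background HSC also held more Elane (62.3 against 1.80 CPM, 5.20 ± 1.53, edgeR adjusted p = 0.0329), Cpa3 (4.53 ± 1.06), Gzmb (4.36 ± 0.86) and Ms4a2 (4.20 ± 0.90), which are known from granulocytes and mast cells. Mature neutrophil genes averaged 58.9 counts per M in CNS HSC replicate 4 and 7.28 to 10.4 in the other CNS HSC libraries. H2-Ab1 (300.0 against 3180 CPM, -3.40 ± 0.91), Naaa (-3.51 ± 0.85) and Flt3 (74.3 against 555 CPM, -2.90 ± 0.52) were lower.

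Against LK, CNS HSC held more RNA of macrophage genes. On genes above background C1qa (74.9 against 1.79 CPM, 5.41 ± 1.47), C1qb (4.96 ± 1.14), C1qc (4.91 ± 1.20), Fcrls (4.28 ± 1.17), Lgmn (4.25 ± 0.88) and Rnase4 (3.79 ± 1.03) rose, with edgeR adjusted p = 0.0338 for C1qa. Of 16 microglia genes 9 rose, 13 adjusted over the list alone (median 2.85, camera adjusted p = 0.000229; adjusted p = 0.474 with an estimated correlation), and of 8 border macrophage genes 7 (median 3.23, camera adjusted p = 0.000104; adjusted p = 0.452 with an estimated correlation). Microglia genes averaged 132 counts per M in CNS HSC replicate 1 and 10.5 to 19.8 in the other CNS HSC libraries. Flt3 fell by 1.87 ± 0.50 and Cst7, a protease inhibitor, by 1.95 ± 0.40. The histone genes Hist1h2ae, Hist1h2ad and Hist1h2ah, uncertain as near copies, fell by 1.42 to 1.47, and so did AC135509.1 by 1.52. Type I interferon genes were higher in 28 of 29 cases; 13 rose, 19 adjusted over the list alone (median 1.07, camera adjusted p = 7.02e-10; adjusted p = 0.452 with an estimated correlation). Between LMPP and LK they were higher in 29 of 29 cases; 8 rose, 26 adjusted over the list alone (median 1.36, camera adjusted p = 9.52e-37; adjusted p = 0.0259 with an estimated correlation). Interferon gamma and antigen presentation genes had a median of 0.83 there, 18 adjusted over the list alone (camera adjusted p = 1.98e-16; adjusted p = 0.0259 with an estimated correlation). Mast cell genes were lower in LMPP than in LK in 8 of 8 cases, 5 adjusted over the list alone (median -2.33, camera adjusted p = 3.45e-10; adjusted p = 0.0259 with an estimated correlation). Ribosomal protein genes were lower in HSC than in LMPP, and 34 of 38 fell (median -1.03, camera adjusted p = 1.38e-22; adjusted p = 0.59 with an estimated correlation).

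In the principal test edgeR called 0 genes between CNS HSC and LK (5467 at an unadjusted p under 0.05), 2 between LMPP and LK (Ly6a and Xcr1) and 46 between HSC and LMPP, 3 higher and 43 lower in HSC. Closest to the threshold for HSC and LK were Cst7, Mrc1 (55.7 against 4.42 CPM), Ly6a, Hist1h2ad and Lgmn, each with edgeR adjusted p = 0.0695. Kit differed there by -1.15 ± 0.57 (edgeR adjusted p = 0.375). The test on genes above background called 434 higher and 807 lower, 31 and 25, and 872 and 1189. DESeq2 called 959 and 1398, 224 and 91, and 6415 and 2051. This scaling moved the comparisons by 0.69, -0.04 and 0.74 log2, and with background as a covariate the counts were 1, 41 and 23. In the principal test HSC and LK differed by 5390 genes without CNS HSC replicate 1, 292 without CNS LK replicate 1 and 1 without CNS HSC replicate 2. LMPP and LK differed by 0 genes without CNS LK replicate 4 and by 1 without CNS LMPP replicate 3 or without CNS LK replicate 1, 2 or 3. HSC and LMPP differed by 6413 genes without CNS HSC replicate 1, and by 6, 6 and 5 without CNS HSC replicate 2, 3 or 4. They differed by 82, 10, 7 and 93 without CNS LMPP replicate 1, 2, 3 or 4. CNS HSC replicate 1 had the lowest background of its group, 3.44% beside 12.2 to 24.2%. Leaving it out, which gave 5390 and 6413 genes, thus also set HSC further apart from LK and LMPP in background. How many of these calls follow background was not tested.

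**Figure D4:**
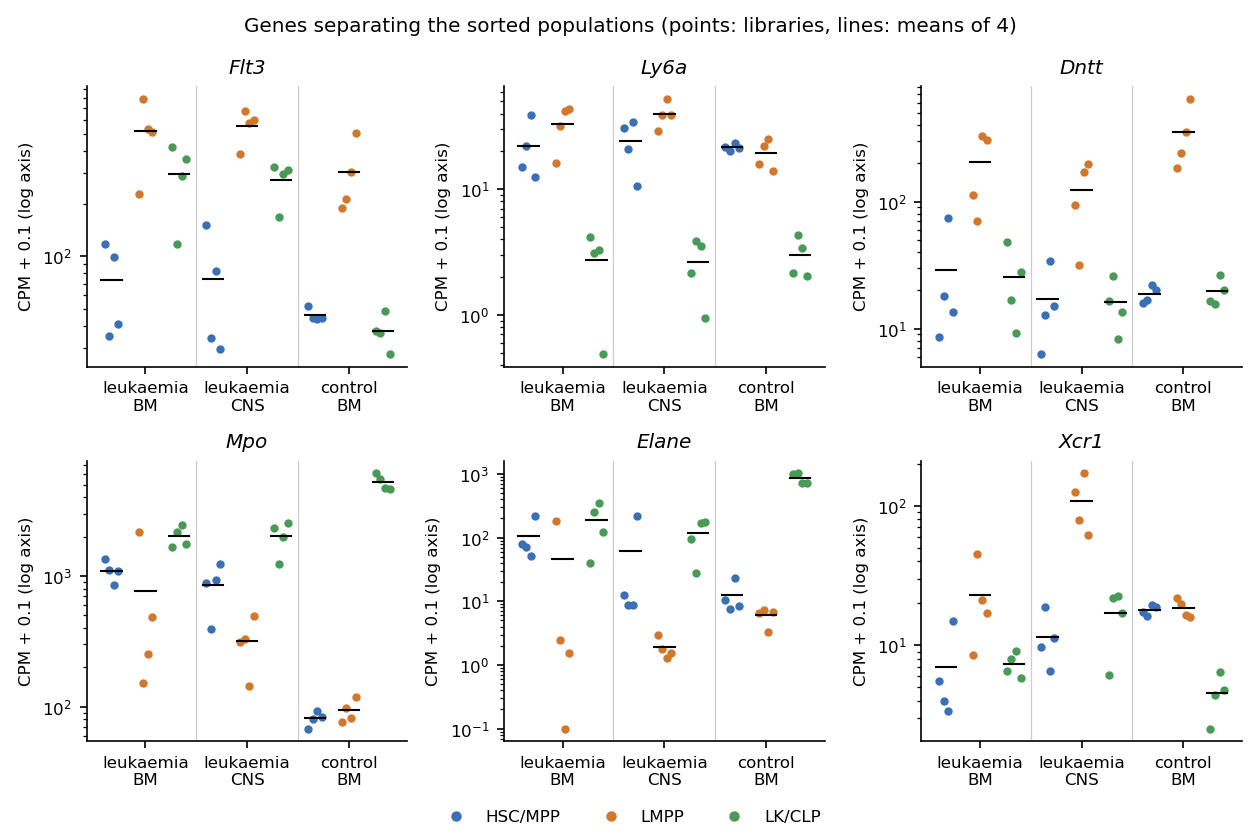
CPM plus 0.1 on a log axis of Flt3, Ly6a, Dntt, Mpo, Elane and Xcr1 in the 9 groups, 1 point per library and a bar at each mean; the leukaemia and control tables were scaled separately. Elane averaged 871 CPM in control LK and 12.3 CPM in control HSC, and in BM leukaemia cells 190 and 106 CPM.

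In control BM, LK cells were rich in granule genes. Elane, neutrophil elastase, was at 871 CPM in LK and 12.3 CPM in HSC (log2 fold change -6.10 ± 0.33 on genes above background, edgeR adjusted p = 3.16e-10), and 5.90 CPM in LMPP (-7.19 ± 0.36). Mpo, myeloperoxidase, was at 5206 CPM in LK and 81.3 CPM in HSC (-6.00 ± 0.28), and Ctsg (-4.75 ± 0.25), Prtn3 (-4.19 ± 0.18), Plac8 (-3.76 ± 0.24) and Car1 (-4.12 ± 0.21) fell with it. Mecom (147 against 22.0 CPM, 2.74 ± 0.16) and Hlf (2.91 ± 0.19), which mark stem cells, rose in HSC over LK. LMPP held more Dntt, the enzyme that adds nucleotides at antigen receptor joins, than LK (356 against 19.6 CPM, 4.18 ± 0.32) or HSC (18.6 CPM, -4.55 ± 0.40 for HSC against LMPP in the principal test, edgeR adjusted p = 8.28e-09). Flt3 was at 46.3 CPM in HSC, 302 CPM in LMPP and 37.7 CPM in LK. It was lower in HSC than in LMPP (-2.97 ± 0.35, edgeR adjusted p = 1.93e-06), while against LK its log2 fold change was -1.33 ± 0.33 in the principal test and 0.30 ± 0.25 on genes above background. Ly6a rose over LK in HSC (2.93 ± 0.26) and LMPP (2.76 ± 0.26), and Kit lay at -0.55 ± 0.16 and -0.73 ± 0.16 on genes above background, at -2.21 ± 0.34 and -2.18 ± 0.34 in the principal test and at 0.47 and 0.030 with quantile scaling. Apoe (1.74 ± 0.27) and Tgm2 (1.29 ± 0.22) were higher in HSC than in LMPP; H2-Ab1, Mpeg1, Il12a and Hbb-bt were lower, by -2.46 to -2.02. Myl10 (4.03 ± 0.20), Hbb-bt (3.37 ± 0.24) and Chga (3.02 ± 0.25) rose in LMPP over LK. Igkc, an immunoglobulin light chain gene, was at 885 CPM in HSC against 2.19 CPM in LK (8.64 ± 1.06), with 2765 CPM in replicate 3 and 211 to 294 CPM in the other libraries, and Jchain at 229 against 1.15 CPM (7.63 ± 1.21), with 716 CPM in replicate 3 and 60.9 to 76.5 CPM in the others.

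Of 38 oxidative phosphorylation genes 38 fell in HSC against LK (median -1.49, camera adjusted p = 4.8e-13; adjusted p = 0.131 with an estimated correlation) and 38 in LMPP against LK (median -1.25, camera adjusted p = 4.89e-13; adjusted p = 0.127 with an estimated correlation). Ribosomal protein genes fell in HSC against LK in 38 of 38 cases (median -1.62, camera adjusted p = 2.06e-14; adjusted p = 0.328 with an estimated correlation). Of 14 HSC genes 11 rose and 2 fell in HSC against LK (median 1.66, camera adjusted p = 7.74e-05; adjusted p = 0.109 with an estimated correlation). Against LMPP 5 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.55, camera adjusted p = 1.39e-09; adjusted p = 0.013 with an estimated correlation). Gata2, a stem cell regulator, rose there from 46.3 to 121 CPM (1.39 ± 0.13, edgeR adjusted p = 8.53e-06). Of 27 granulocyte genes 15 fell and 6 rose in HSC against LK (camera adjusted p = 4.81e-06; adjusted p = 0.109 with an estimated correlation). Histone genes were lower in HSC than in LMPP; 11 fell, 22 adjusted over the list alone (median -0.98, camera adjusted p = 7.52e-23; adjusted p = 0.179 with an estimated correlation). The 3 sort markers Kit, Ly6a and Flt3 tested lower in HSC than in LMPP on genes above background (camera adjusted p = 0.0134; adjusted p = 0.179 with an estimated correlation), with a median above 0 at 0.17, since Flt3 alone fell. Megakaryocyte genes were higher in HSC, with 6 of 7 against LK (median 1.44, camera adjusted p = 0.00575; adjusted p = 0.309 with an estimated correlation). Type I interferon genes were higher in LMPP than in LK, 10 of 11 (median 0.70, camera adjusted p = 0.0198; adjusted p = 0.2 with an estimated correlation).

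The principal test, over 41609 genes, called 8287 higher and 10402 lower in control HSC against LK, 6458 and 10224 in LMPP against LK, and 10 and 39 in HSC against LMPP. On genes above background the counts were 4115 and 3769, 3869 and 3527, and 65 and 184, and this scaling moved the comparisons by 1.64, 1.47 and 0.16 log2. DESeq2 called 5326 and 10763, 4960 and 10433, and 14 and 109. With the mouse as a block, 11 and 30 genes differed between HSC and LMPP, and 34 and 78 on genes above background. That comparison gave 208 genes in the principal test without control LMPP replicate 1, 56 without LMPP replicate 2 and 12 without LMPP replicate 3. It gave 19, 25, 26, 22 and 27 without HSC replicate 1, 2, 3 or 4 or LMPP replicate 4. Background was at least 14.1% in every HSC and LMPP library of the controls and at most 12.3% in LK, so that it moved with each of the first 2 comparisons; as a covariate it left 2149, 2870 and 114 genes.

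Whether cell type differences in BM depended on disease was tested over both tables. Klf1 averaged 58.6 CPM in control LK against 10.2 CPM in HSC, and 1.49 against 8.10 CPM in leukaemia (edgeR adjusted p = 2.8e-07). Mpo averaged 5206 CPM in control LK against 81.3 CPM in HSC, and 2014 against 1098 CPM in leukaemia (edgeR adjusted p = 6.82e-06); Ctsg (9.29e-07), a granule protease, moved likewise. Aqp1, a water channel of red cells (2.13e-06), Sept8 (3.34e-06) and the protease gene Ctse (3.34e-06) were higher in control LK than in control HSC or LMPP, as was C1qtnf12 (2.39e-06). Ap3s1 (1.56e-05) averaged 81.1 CPM in control LK and 7.00 CPM in HSC, and 121 and 74.1 CPM in leukaemia. All 8 were chosen as those of smallest p, and levels come from separately scaled tables. The test called 5529 of 43483 genes, 4190 with the replicate number as a block, 4657 on genes above background and 13636 by DESeq2. It called 3026 without control LK replicate 1, 3650 and 3205 without BM LK replicate 1 or 2, 11761 without BM LMPP replicate 4 and 8662 without BM LK replicate 4. Both arms carried the fusion, and disease went with the overexpressed microRNA, so that these cannot be told apart. Disease also went with the table, the mouse cohort, background and sex. Xist, expressed from the inactive X, was at 288 to 801 counts per M in controls and 0.0759 to 142 in leukaemia. The Y-linked gene Ddx3y was at 7.82 to 52.4 counts per M in leukaemia and at most 1.37 in controls, apart from 3.20, 8.69 and 14.5 in the 3 libraries of control mouse 3.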

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

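The tests that weigh the 3 patterns at the end of this part were chosen after the results were seen. In 17 of 153 checks, over 17 measures in 9 groups of 4 libraries, 1 library stood apart. It was the lowest or highest, and its gap from the other 3 was most of the range of its group. Independent values from a normal distribution would give 1 in 20, or 7.65. The measures share libraries and their distribution was not tested, so 17 beside 7.65 carries no conclusion.

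In the control libraries, HSC replicate 4 had the fewest counts, 3.55 M beside 8.14 to 8.83 M, and the fewest genes with at least 10 counts, 30826 beside 40120 to 41922. Its 10 highest genes took 45.1% of counts beside 39.5 to 40.2%. Genes of B and plasma cells averaged 208 counts per M in HSC replicate 3 beside 25.0 to 29.0. In LK replicate 3, 25.3% of counts had no symbol beside 35.9 to 37.7%, microglia genes averaged 11.5 counts per M beside 9.03 to 9.43, and border macrophage genes 24.2 beside 19.1 to 19.7. In LK replicate 4, immediate early and heat shock genes averaged 8.38 counts per M beside 9.83 to 10.1.

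In the leukaemia libraries, BM HSC replicate 4 carried 26.5% background beside 8.97 to 9.12%. Mature neutrophil genes averaged 221 counts per M in BM LMPP replicate 1 beside 2.33 to 4.12, and 58.9 in CNS HSC replicate 4 beside 7.28 to 10.4. Erythroid genes averaged 49.3 counts per M in CNS HSC replicate 4 beside 9.96 to 16.7. They averaged 19.9 in BM LK replicate 1 beside 8.84 to 9.56 and 33.7 in CNS LK replicate 1, of the same mouse, beside 8.27 to 11.0. Cell cycle genes averaged 100.25 counts per M in CNS LMPP replicate 4 beside 42.6 to 47.9. CNS HSC replicate 1 held microglia genes at 132 counts per M beside 10.5 to 19.8, and Xist at 142 beside 7.12 to 11.7.

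Cell type differences in BM differed between the leukaemia and control arms for 5529 genes by the interaction test of edgeR. The 8 genes of smallest p were Klf1 (edgeR adjusted p = 2.8e-07), Ctsg (9.29e-07), Aqp1 (2.13e-06), C1qtnf12 (2.39e-06), Sept8 (3.34e-06), Ctse (3.34e-06), Mpo (6.82e-06) and Ap3s1 (1.56e-05).

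Immediate early and heat shock genes were higher in CNS than in BM. RNA of macrophages in the CNS sort stays open: in LK the list lay at a mean per-mouse median of 0.42 ± 0.12 (SE, n = 4), beside 0.095 ± 0.32 for microglia genes and 0.46 ± 0.32 for border macrophage genes. Handling of CNS tissue before sorting stays open too: the list was above 0 in 12 of 12 mice, as handling would give, but tissue and handling cannot be told apart in this design. An effect of the niche itself was not tested apart from it and also stays open.

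Microglia and macrophage genes were higher in CNS. RNA of female cells may account for CNS HSC replicate 1, although the sort was for stem and progenitor cells. Xist was at 142 counts per M there, more than in any other leukaemia library. Ddx3y was at 38.3 counts per M there, beside 43.7 in BM HSC replicate 1 of the same mouse. Where female cells would come from was not tested. For CNS LMPP, Xist rose over BM by 1.43 counts per M where 8.69 would follow from C1qa at the ratio of that library, 16.5% of it, and 1 library cannot set the ratio for other cells. Cells of male origin or the leukaemia cells themselves therefore remain open there and cannot be told apart from RNA of female cells. C1qa was at 74.9 CPM in CNS HSC and 1.79 CPM in CNS LK. Microglia genes averaged 132 counts per M in CNS HSC replicate 1 beside 10.5 to 19.8 in the other CNS HSC libraries.

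Neutrophil granule genes were lower in CNS than in BM. Scaling was argued against, since the median of the list nearest 0 over 8 settings was -1.74, with quantile scaling. Mature neutrophils in the BM sort stay open: 5 late neutrophil genes had a median of -0.21 beside -2.88 to -2.06 for 6 granule genes, but 4 of them averaged only 1.91 to 9.97 CPM in BM, and Csf3r, at 63.0 CPM in CNS, has a high baseline. Immature granulocytes in the BM gate, and lower granule gene expression of leukaemia cells in CNS, stay open and were not tested apart. BM LMPP replicate 1 held much of the level in BM LMPP, and the list lay above 0 in 3 of 12 mice, LMPP mice 2 and 3 (1.23 and 1.18) and HSC mouse 4 (0.19).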

How the results depend on the processing

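The settings chosen after seeing the data were the filter on background with or without the mouse as a block, the background covariate, limma-trend with pseudocount 1, leaving out each mouse, and the omission of BM LMPP replicate 3 and CNS HSC replicate 1; the others were planned. Unless a reason is given, the cause of a change was not tested. For leukaemia cells, counts of genes called follow the order HSC against LK, LMPP against LK and HSC against LMPP, and beside them stand the principal counts of 0, 1 and 2 in BM and 0, 2 and 46 in CNS. The niche counts were 0 over all cell types and in HSC, LMPP and LK.

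Without the filter on low counts the niche test called 5 genes over all cell types, HSC against LMPP in BM gave 12, and CNS gave 224, 11 and 80. DESeq2 called 79 niche genes over all cell types and 9 in LMPP; cell types gave 83, 28 and 265 in BM, 2357, 315 and 8466 in CNS and 123 for control HSC against LMPP, where the principal test gave 49. DESeq2 called 13636 genes for the dependence on disease against 5529. It turned Kit between BM HSC and LMPP to 0.046 from -0.32 and Ly6a between control HSC and LMPP to -0.039 from 0.02. Array weights in limma-trend called 3520 niche genes over all cell types, 5257 in HSC, 823 in LMPP, 9 in LK and 272 for the dependence on cell type. They gave 201, 155 and 20958 in BM, 7897, 5989 and 19111 in CNS, and 19617 for disease. They turned the niche log2 fold changes in HSC of Hs6st1 to -0.094 from 0.84 and of Tgfbr1 to -0.33 from 1.76. Kit turned to 0.19 between control HSC and LMPP and, for LMPP against LK, to 0.065 in BM and 0.59 in CNS. The weights were estimated from the same libraries, whose spread differed.

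Limma-trend with pseudocount 1 gave 1 gene for BM HSC against LMPP, 467 in CNS and 30 in controls, and Kit between control HSC and LMPP at 0.056 against -0.03. With pseudocount 5 it called 1 niche gene in LMPP, 11 for BM HSC against LMPP, 6 for CNS LMPP against LK and 904 for CNS HSC against LMPP, with Kit at 0.0555. Quantile scaling called 2 niche genes in LMPP, 0 and 5 for BM LMPP against LK and HSC against LMPP, 1710, 26 and 1779 in CNS and 261 for control HSC against LMPP. It turned control HSC against LK for Flt3 to 0.095 from -1.33 and for Kit to 0.47 from -2.21, control LMPP against LK for Kit to 0.030 from -2.18, and HSC against LMPP for Kit to 0.44 in controls and 0.33 in BM. Kit between BM HSC and LK became 0.017 against -0.44. Median centring called 0 and 10921 genes for BM LMPP against LK and HSC against LMPP, 1, 1 and 29 in CNS and 20 for control HSC against LMPP. It turned Auts2 between BM HSC and LMPP to -0.18 from 1.82, and Kit to 0.018 between control HSC and LMPP and 1.07 and 0.058 for LMPP against LK in BM and CNS. With only the groups compared, BM LMPP against LK gave 5 genes and HSC against LMPP 985. CNS gave 123 and 9, control HSC against LMPP gave 27, and Ly6a there turned to -0.0086. Fewer libraries then set the spread.

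With the mouse as a block, 54 niche genes were called over all cell types and 1 in LK; Kit between control HSC and LMPP turned to 0.0063, and no other niche or control count moved by over 1.5 times. Leukaemia libraries of different cell types share only a replicate number. Their deviations correlated at a median of -0.13 in BM and 0.01 in CNS, where 2 and 1 of 12 pairs were the best match. This block gave 3, 3 and 50 genes in BM and 0 and 5 for CNS LMPP against LK and HSC against LMPP. The first number of the mouse identifier as a block gave 14, 20 and 172 in BM and 5262, 50 and 14765 in CNS, with Kit between CNS LMPP and LK at 0.024.

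On genes above background, fewer genes were tested and the scaling moved. BM HSC against LK gave 5 genes and HSC against LMPP 11, CNS gave 1241, 56 and 2061, and controls gave 7884, 7396 and 249 against 18689, 16682 and 49. Gene lists passed 13 in control HSC against LK against 27, 17 in BM against 29 and 12 in CNS against 26; for HSC against LMPP they passed 18 in BM against 28 and 15 in CNS against 29. Flt3 in control HSC against LK was 0.30, and Kit between HSC and LMPP 0.18 in controls and 0.13 in BM. The niche fold changes of HSC and LMPP correlated across genes at 0.30 against 0.17 for all genes, and those of LMPP and LK at 0.19 against -0.00068. With a mean count of at least 100 the correlations were 0.47 for HSC and LMPP, 0.0021 for HSC and LK and 0.23 for LMPP and LK. With the mouse as a block on genes above background, 386 niche genes were called over all cell types, 294 in LMPP and 1 in LK, and 59, 1 and 1 without the mice of BM LMPP replicate 3 and CNS HSC replicate 1. Controls gave 7700, 7205 and 112, disease 3588, and 13 lists passed for control HSC against LK. The niche correlations were 0.28, 0.0016 and 0.16 against 0.17, -0.055 and -0.00068, with Flt3 at 0.31 in control HSC against LK and Kit at 0.19 between control HSC and LMPP.

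With the background level as a covariate, 6 niche genes were called over all cell types, 1 in HSC and 4 in LMPP. Cell types gave 0 for BM HSC against LMPP, 1, 41 and 23 in CNS and 2149, 2870 and 114 in controls, and disease gave 2469. In controls the covariate parted LK from HSC and LMPP, but not HSC from LMPP. It turned Flt3 in control HSC against LK to 0.58, and Kit to 0.023 for BM HSC against LK, 0.28 for control HSC against LMPP and 0.53 for BM HSC against LMPP. Without BM LMPP replicate 3 and CNS HSC replicate 1 the principal test gave 1, 0 and 16 genes in BM and 5254, 10 and 6350 in CNS. Most of these were lower in HSC: 5225 of the 5254 and 5952 of the 6350. CNS HSC replicate 1 also had the lowest background of its group. Kit between BM LMPP and LK turned to 0.0094 from -0.13 and Tgfbr1 by niche in HSC to -0.12.

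With an estimated correlation, gene lists passed 3 times for the niche over all cell types against 23 in the principal test. In HSC, LMPP and LK they passed 0 times against 15, 21 and 14. For control cell types 0 passed against 27, 23 and 20, for BM 0 against 29, 13 and 28, and for CNS 0, 8 and 0 against 26, 21 and 29.

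Leaving out each library in turn, the principal niche count was 0 to 63 over all cell types and 0 to 22 in LMPP. It was 0 to 2, 0 to 42 and 0 to 6 for BM cell types, 0 to 5390, 0 to 2 and 5 to 6413 for CNS, 12 to 208 for control HSC against LMPP and 3026 to 11761 for disease. The libraries concerned are named beside each count in the report. Kit ranged from -0.21 to 0.24 between control HSC and LMPP, -0.57 to 0.0093 between BM HSC and LMPP, and -0.28 to 0.0096 and -0.30 to 0.14 for LMPP against LK in BM and CNS. Ly6a between control HSC and LMPP ranged from -0.13 to 0.16 and Tgfbr1 by niche in HSC from -0.12, without CNS HSC replicate 1, to 2.11. Of 237 named genes, DESeq2 left 147 on the same side of the threshold with the same direction, moved 71 past it and turned 2; the mouse as a block left 198, moved 30 past it and took 8 below it. Over all libraries left out in turn, 2814 values stayed, 71 moved past the threshold, 62 fell below it and 11 turned. The depth of BM LMPP replicate 3, 1.91 M counts, and the background of HSC libraries limit what weakly expressed genes can show.

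Other splits of the same libraries were tested, 35 for each pair of groups of 4 and, where more exist, 60 or 100 drawn, with the real split counted among those as large. Where the principal test gave a real count of 0 every split is as large, so that the splits decide nothing there. This holds for the niche, with 60 of 60 splits over all cell types (highest other 0), 35 of 35 in HSC (7043), LMPP (0) and LK (3399), and 60 of 60 for the dependence on cell type (0). It also holds for HSC against LK in BM (35 of 35, highest other 1) and CNS (35 of 35, highest other 0). Chance cannot be excluded for BM LMPP against LK (3 of 35, real 1, highest other 50), nor for CNS LMPP against LK (3 of 35, real 2, highest other 9721) and HSC against LMPP (2 of 35, real 46, highest other 11376). For BM HSC against LMPP the share was the smallest that 35 splits can give (1 of 35, real 2, highest other 1), but 2 calls beside 1 carry no conclusion, as the count was 0 without any 1 of 6 of the 8 libraries. In controls the real split was the largest for all 3 comparisons. The shares were 1 of 35 for HSC against LK (real 18689, highest other 0) and 1 of 35 for LMPP against LK (real 16682, highest other 173). For HSC against LMPP it was also 1 of 35 (real 49, highest other 2). Control libraries pair by mouse, which these splits ignore, so they do not exclude chance. For the dependence on disease the share was 1 of 60 (real 5529, highest other 2). On genes above background the highest other was 52 beside 4657. Labels were permuted in each cell type by itself, which parted the libraries of a control mouse, so chance was not excluded for whole mice.

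With the tissues swapped within mice, the real labels gave the most calls in the paired niche test over all cell types on genes above background (1 of 100, real 386, highest other 87). That share is the smallest that the draws can give and was not adjusted over comparisons. The filter was chosen after seeing the data, and the principal test called 0 genes, so chance is not excluded. On all genes 2 of 60 swaps drawn from 2048 were as large (real 54, highest other 727), too few draws to place the share firmly under 0.05. The split with 727 calls, several times the real count, points to a structure of the samples. In LMPP the 8 swaps are too few for a share under 0.05, with a real count of 294 and a highest other of 1. On genes above background the real split was the largest for BM HSC against LK (1 of 35, real 5, highest other 0). The same held for BM HSC against LMPP (1 of 35, real 11, highest other 0). These few calls came from a filter chosen after seeing the data and carry no conclusion. The principal test called 0 and 2 there. Chance cannot be excluded for BM LMPP against LK (2 of 35, real 1, highest other 27). In CNS the real split was the largest for LMPP against LK (1 of 35, real 56, highest other 0). That share is the smallest that 35 splits can give and was not adjusted over comparisons. The principal test gave 2 calls there beside a highest other of 9721. Chance cannot be excluded for CNS HSC against LMPP (2 of 35, real 2061, highest other 5028). For CNS HSC against LK the real split was the largest (1 of 35, real 1241, highest other 1044), but a split by background came close, so that the share carries no conclusion. In controls the real split was the largest among all splits for all 3 (1 of 35 each, real 7884, 7396 and 249, highest other 0, 699 and 0). Control libraries pair by mouse, however, and the 8 splits that part every mouse are too few for a share under 0.05. The highest other of these was 0 for all 3 on genes above background, and 0, 0 and 2 in the principal test. The splits with 699 and 173 calls, and those with 7043 and 3399 for the niche, joined libraries of a mouse.

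Several of these highest splits followed the background of the libraries. For the niche in HSC and LK and for CNS LMPP against LK and HSC against LMPP, the splits with 7043, 3399, 9721 and 11376 calls put the 4 libraries of highest background on the same side. In HSC these were BM replicate 4 and CNS replicates 2, 3 and 4, at 12.2% or more beside 9.12% or less. The split with 5028 calls on genes above background did so too, with 8.50% or more beside 3.44% or less. In the split with 1044 calls the sides also parted by background, but narrowly, at 8.69% or more and 8.29% or less. Such calls point to a structure of the samples. With the background as a covariate the CNS counts were 1, 41 and 23.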

Other observations

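The dendritic cell lists were written before their own test but after the niche genes were seen, and how their tests are read and the comparison of fusion targets between tables were chosen after seeing the data. Genes of conventional dendritic cells, which capture and present antigen, were higher in CNS than in BM LMPP in 18 of 18 cases. In the paired test on genes above background 11 rose, 13 adjusted over the list alone, with a median log2 fold change of 1.36. The endosomal gene Rab7b rose by 1.91 ± 0.33 and the interferon-inducible gene Ifi205 by 1.73 ± 0.29, each with edgeR adjusted p = 0.016. Wdfy4, needed for cross-presentation, was at 1457 CPM in BM and 2905 CPM in CNS (1.14 ± 0.26). The hypothesis that these genes rise in CNS LMPP was not decided: camera gave p = 0.003171 with an estimated correlation, but on the 4 pairs whose niche genes had led to the list. In HSC and LK pairs p was 0.134 and 0.083, and without LMPP mouse 1 or 3 this fit called 0 niche genes in LMPP. Per-mouse medians were 2.21, 0.53, 2.21 and 1.04 in the LMPP mice, and LMPP mouse 4 was above 0 while its microglia median was -0.62. Over all cell types 11 of 12 mice were above 0 (mean 0.82 ± 0.21, SE). Whether more dendritic-like leukaemia cells or RNA of other cells may bring this was not tested.

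Genes of plasmacytoid dendritic cells, the main makers of type I interferon, were lower in CNS LMPP in 13 of 16 cases (median -0.56). The hypothesis that they fall was not decided: p was 0.00042 with the preset correlation of camera and 0.116 with an estimated correlation. Tcf4, their lineage regulator, differed by -0.64 and Spib by -1.40, while Tlr9 differed by 0.91.

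Between leukaemia and control BM, 8 targets of the Kmt2a fusion were compared in each cell type by an exact two-sided permutation test of 4 against 4 libraries. Its smallest possible p is 0.0286, which becomes 0.0429 adjusted by Benjamini-Hochberg over 24 tests. Hoxa10 was higher in leukaemia HSC, LMPP and LK, by 2.37, 2.36 and 3.10 on the log2 scale, each at this smallest p and in 4 of 4 libraries. Meis1, a partner of Hoxa genes, was lower in all 3 types, at -1.80, -1.77 and -1.80, and Mef2c was higher in all 3. Hoxa9 was higher in LMPP by 1.33 and in LK by 1.98. Groups did not overlap for 2 higher and 1 lower gene in HSC, 6 and 1 in LMPP and 5 and 1 in LK, where chance gives 2.86% of genes. The 8 genes are only a part of the fixed list of targets. The share of all genes whose groups did not overlap was not computed, so these counts do not set the targets apart from other genes. The overexpressed microRNA, table, mouse cohort, sex and background went with disease in every one of these values.

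Cell type differences in leukaemia and control BM were set side by side across 10348 genes above background, which are not independent replicates. HSC against LK correlated between leukaemia and control at a Spearman rho of 0.71 in BM and 0.76 in CNS, LMPP against LK at 0.076 and 0.16, and HSC against LMPP at 0.46 and 0.41. Of genes called in CNS leukaemia and in control HSC against LK, 97 were higher in both where 34.5 would overlap by chance, and 684 were lower in both where 290 would. Background differed by cell type in both tables and was not removed from these values. For HSC against LK it ran in the same direction in both. For LMPP against LK it ran in opposite directions. Its means in LMPP and LK were 2.68 and 5.48% in leukaemia BM, 3.55 and 4.78% in CNS, and 21.5 and 9.68% in controls. The low correlation for LMPP against LK thus cannot be told apart from background. The overlaps given for chance assume independent calls, which shared background would break.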
